A study of Mus musculus with 9 samples.

How the data were processed

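Chromatin immunoprecipitation with sequencing was carried out on mouse MLL-ENL leukemia cells, a myeloid leukemia driven by a fusion of the Kmt2a and Mllt1 genes. The series holds 9 libraries from 3 immunoprecipitations (H3K27me3, H3K4me3 and the M2 antibody against the Flag tag) in each of 3 genotypes. The genotypes are a floxed line, a deleted line (labelled ΔERT2) and a deleted line that also carries Flag-tagged Hhex, called the rescue line here. The labels do not name the floxed gene; the series title and the tagged gene are the ground for reading it as Hhex. Per the labels' protocols, chromatin was sheared by sonication, the histone marks were precipitated with polyclonal antibodies on protein A beads, and the tagged protein with anti-Flag beads. Each group has 1 library, so no difference between groups has a replicate check and no test between groups was made.

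The 6 histone files hold whole-number counts per gene as deposited by the authors, not normalised, with an Entrez identifier, a symbol and a length in 27179 rows each. The submitters' processing notes name featureCounts, MACS2 and the build mm10 with no version; the aligner is not given in the sources used here. The lengths in the file columns show that H3K27me3 was counted over whole gene spans, with a median of 12257 bp. H3K4me3 was counted in a window of 301 bp per gene, except for 2 genes, and the position of that window is not given in the sources used here. Rows without a symbol (568, holding 0.608% to 0.739% of the counts of a library) were left out of library totals and comparisons. The 3 Flag files hold summit positions with a −log10 score, as deposited by the authors; MACS2 writes summit files of this layout. They hold 475, 220 and 429 summits for floxed, deleted and rescue. The scores are the authors' and were used to rank or filter summits within a list only. No input library was used here.

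Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the same assembly as mm10, matched on the Entrez identifier for 25275 of 26611 named genes. This table gives gene starts and ends without strand or exons, so transcription starts could not be set. The planned distance to a transcription start was therefore replaced by the distance to the nearer gene end, and the planned nearest gene by the gene whose span held the summit or lay within 10 kb. Whether a summit lies in an exon or an intron was not analysed here, and neither was GC content.

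Counts were divided by the total of named genes of their library and given as CPM. A gene was called lower or higher when its CPM ratio was at least 1.5 in that direction and the 95% exact conditional binomial (Clopper-Pearson) interval of the ratio excluded 1. This was applied to genes with a mean of at least 20 counts over the 3 libraries of the mark, which are the genes called measured. The intervals cover counting error only. Log2 ratios used a prior count of 1 at the mean library size. With 1 library per group the rule describes these libraries, not the conditions.

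The precision differs between marks. The H3K27me3 libraries hold 2444487, 2535576 and 4203349 counts in named genes for floxed, deleted and rescue, and the H3K4me3 libraries 645240, 420701 and 395133. On simulated Poisson counts for the 10602 measured H3K27me3 genes of deleted against floxed, the rule recovered 22 of 25 genes lowered 2-fold and 23 of 25 lowered 3-fold, 5-fold or 10-fold, and 24 of 25 raised 2-fold and 25 of 25 raised further. The 2 genes missed at 5-fold and at 10-fold had dropped under the filter on mean counts, so the pass mark of 95% at 10-fold, first missed at 92%, was then applied to the genes past the filter. For H3K4me3, with 6682 genes in that step, 23, 24, 23 and 23 of 25 lowered genes and 25 of 25 raised genes were recovered at these folds. Among unchanged genes in the same simulations, the rule called 1.70% for H3K27me3 and 2.48% for H3K4me3.

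Gene lists were fixed before the data were examined: CDK inhibitors, the Cdkn2a neighbourhood, the HoxA, HoxB, HoxC and HoxD clusters, developmental transcription factors, PRC2 genes, PRC1 genes, MLL fusion targets, granulocyte and monocyte maturation, stem and progenitor genes, B-cell, T-cell and NK-cell, erythroid and megakaryocyte, mast cell, basophil and eosinophil, stromal and endothelial, VEGF signalling, p53 targets, proliferation, housekeeping, interferon-stimulated, germline, neuronal and olfactory receptor genes. Each list median was placed among 10000 random lists of the same size matched on mean level, as a description of these libraries. The random lists drew genes singly. For lists with adjacent genes, such as the Hox clusters, a percentile can therefore overstate how far the list stands out. A match on read density (CPM per kb) was added after seeing the data. The genes named in the text were chosen by a rule fixed in advance. It takes Cdkn2a, Cdkn2b and Hhex; for each mark the 10 lower and 10 higher genes of deleted against floxed, and the 5 lower and 5 higher of rescue against deleted, whose intervals lay farthest from 1; up to 4 members of each list, with any Hox or CDK inhibitor gene; the 10 highest-scoring summits of the rescue library alone and any summit within 100 kb of Cdkn2a. Predicted genes, Rik clones and Olfr or Vmn genes were skipped in the ranked parts.

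The deleted library enters both comparisons, so part of any return comes from chance. Unchanged libraries were simulated 100 times with Poisson counts, and library labels were shuffled 100 times within each gene, which keeps the observed spread and any real differences. Flag summits with no floxed or deleted summit within 250 bp were taken as rescue-alone. Not every rescue-alone summit among those chosen by the rule is reported here. The other settings compared, fixed at the same stage as the lists, were edgeR TMM factors, DESeq2 size factors (both for scaling only), scaling to a background list, no filter or a mean of at least 100 counts, a 2-fold rule, a prior count of 5, other distances for shared summits, and summits above the median score of their list. For the background list a median ratio over its members was planned, and pooled counts took its place after the data were seen. The reason was that 0 of 30 housekeeping genes were measured for H3K27me3 and 1 of 1123 olfactory receptor genes for H3K4me3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.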

Results

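H3K27me3, the mark placed by Polycomb repressive complex 2 (PRC2), H3K4me3, a mark of active promoters, and the binding of Flag-tagged Hhex were profiled in MLL-ENL leukemia cells of 3 genotypes, with 1 library for each of the 9 combinations. The series title places the question on whether Hhex is needed for PRC2 repression of Cdkn2a, and the floxed, deleted and rescue lines address it. Named genes held 2444487 (floxed), 2535576 (deleted) and 4203349 (rescue) H3K27me3 counts, and 645240, 420701 and 395133 H3K4me3 counts. All values come from single libraries without replicates, and every interval is a 95% interval. Intervals of ratios and of shares of counts cover counting error only. Those of shares of genes or summits take genes or summits as independent draws.

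Hhex itself (chromosome 19, 37434841 to 37440731, mm10) had 332, 385 and 487 H3K27me3 counts over its whole span in floxed, deleted and rescue, and no pair differed by the size rule. Its H3K4me3 window had 60, 68 and 130 counts. The H3K4me3 ratio was 1.74 (1.21 to 2.5) for deleted against floxed and 2.04 (1.51 to 2.77) for rescue against deleted. Neither count is limited to the deleted part of the gene, so neither checks the deletion.

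Cdkn2a, which encodes the cell cycle inhibitors p16 and p19ARF, carried less H3K27me3 in the deleted library than in both others. Over its span on chromosome 4, 89274473 to 89294619, there were 575 counts in floxed, 164 in deleted and 1060 in rescue. The ratio was 0.275 (0.230 to 0.328) for deleted against floxed, a log2 ratio of -1.86, and 3.90 (3.30 to 4.62) for rescue against deleted, a log2 ratio of 1.96. The adjacent Cdkn2b, which encodes the inhibitor p15 (chromosome 4, 89306289 to 89311032), followed the same course with 62, 5 and 91 counts. Its ratio was 0.0777 (0.0244 to 0.191) for deleted against floxed and 11 (4.54 to 34.6) for rescue against deleted. Cdkn1c, another CDK inhibitor gene, had 128, 82 and 248 counts and a ratio of 0.618 (0.462 to 0.821) in deleted against floxed. In the CDK inhibitor list, 3 of 4 measured genes were lower in the deleted library, with a median log2 ratio of -1.27, at percentile 0.00 of random lists matched on level and also when matched on read density. Cdkn2c was the member not called, with 95, 86 and 58 counts. Cdkn2a and Cdkn2b are adjacent and random lists draw genes singly, so this percentile does not show a change of CDK inhibitors as a class. In the list of the Cdkn2a neighbourhood, 2 of 4 measured genes were lower, Cdkn2a and Cdkn2b, with a median of -1.10.

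H3K4me3 in the window counted for Cdkn2a was not higher in the deleted library. The window had 46, 20 and 39 counts, a log2 ratio of -0.56 for deleted against floxed that did not meet the size rule, and of 1.02 for rescue against deleted, which did. Both ratios had the same sign as those of H3K27me3, and both rest on the 20 deleted counts. The position of the window is not given, so H3K4me3 elsewhere at Cdkn2a was not measured. Cdkn2b had 0, 0 and 1 H3K4me3 counts, so no ratio can be given at this depth. Cdkn1a had 58, 73 and 52 H3K4me3 counts, with a ratio of 1.93 (1.35 to 2.77) for deleted against floxed. Cdkn2c had 36, 11 and 16, with a ratio of 0.469 (0.215 to 0.941).

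**Figure D1:**
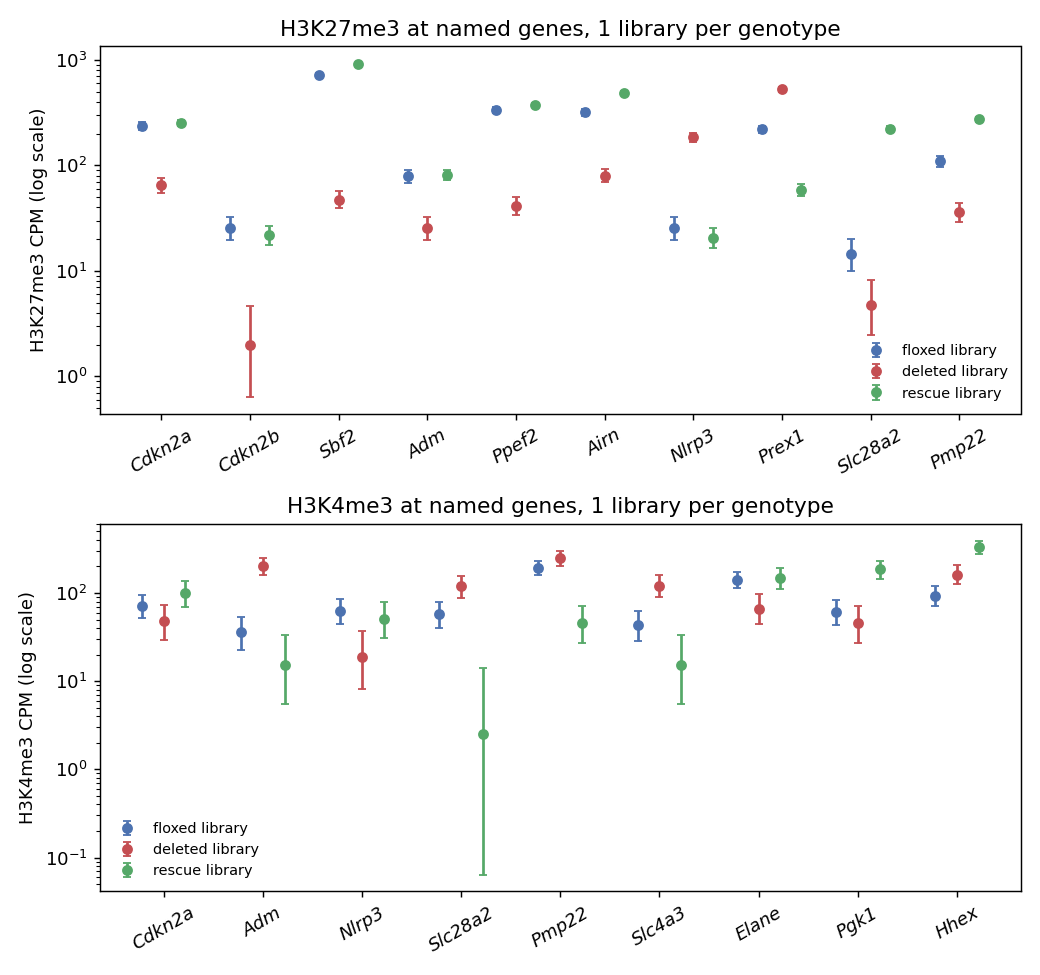
Library-scaled counts (CPM, log scale) of H3K27me3 (top) and H3K4me3 (bottom) at named genes; points are single libraries (blue floxed, red deleted, green rescue) and bars are exact 95% Poisson intervals for counting error. H3K27me3 at Cdkn2a and Cdkn2b was lower in the deleted library than in both others, and at Nlrp3 and Prex1 it was higher.

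H3K27me3 was lower in the deleted library across several long stretches of chromatin. Sbf2, a regulator of phosphoinositide signalling (chromosome 7, 110308011 to 110614934), had 1752, 120 and 3794 counts, a ratio of 0.0660 (0.0544 to 0.0795) for deleted against floxed. Next to it, Adm, which encodes the peptide hormone adrenomedullin, had 193, 65 and 342 counts. On chromosome 5, Ppef2 had 815, 105 and 1567 counts and its neighbour Naaa 141, 7 and 358. On chromosome 1, Chpf had 189, 1 and 359 counts, a ratio of 0.00510 (0.000128 to 0.0288), and its neighbour Tmem198 334, 24 and 568. Adam28, on chromosome 14, had 774, 108 and 1607. Igf2r, an imprinted growth factor receptor gene, and the non-coding Airn that overlaps it had ratios of 0.234 (0.196 to 0.278) and 0.251 (0.214 to 0.294); their counts cannot be separated. Btnl5-ps had a ratio of 0.174 (0.125 to 0.236). Each of these genes was higher again by the size rule in rescue against deleted.

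The opposite course was seen at the inflammasome gene Nlrp3 (chromosome 11, 59541569 to 59566955), with 62, 466 and 87 H3K27me3 counts and a ratio of 7.25 (5.55 to 9.60) for deleted against floxed. Its neighbour Zkscan17 had 12, 48 and 9 counts. Prex1, a Rac exchange factor gene, had 535, 1334 and 246 counts and a ratio of 2.40 (2.17 to 2.66). Thbs1, which encodes thrombospondin 1, had 2, 75 and 19 counts and a ratio of 36.2 (9.67 to 304). Gng2 had a ratio of 2.56 (1.88 to 3.52) and Dcun1d2 2.89 (1.88 to 4.57). Hspbp1, Misp, N4bp3 and Sppl2c, with 9 to 14 floxed counts each, had ratios of 4.03, 4.07, 3.79 and 3.94.

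Of 10604 measured genes, 572 were lower and 500 higher in H3K27me3 in the deleted library than in the floxed library. Counting error simulated with no difference gave 84.2 lower and 81.8 higher genes. The split between lower and higher genes depended on the scaling: it was 1239 lower and 226 higher when libraries were scaled to a background list, which put the median log2 ratio of all genes at -0.16 in place of 0.02. That scaling rests on 101 floxed and 119 deleted counts pooled over 30 genes, so its counting error is large. With a mean of at least 100 counts it was 324 and 107, and with a 2-fold rule 145 and 177.

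In each Hox cluster, long-known Polycomb targets, some genes were lower in H3K27me3 in the deleted library and none higher. In the HoxC cluster 6 of 9 measured genes were lower by the size rule and all 9 had log2 ratios below 0, with a median of -0.68; Hoxc4 had 176, 93 and 282 counts, Hoxc11 220, 129 and 349. In the HoxD cluster 5 of 8 were lower with a median of -0.62, among them Hoxd8 with a ratio of 0.482 (0.357 to 0.647). HoxB had 4 of 10 lower and a median of -0.56, with Hoxb3 at -0.04. In the HoxA cluster 3 of 4 measured genes were lower with a median of -0.78. Hoxa11, with 166, 47 and 380 counts, had a ratio of 0.273 (0.193 to 0.379), and Hoxa10 one of 0.597 (0.483 to 0.736). Hoxa9 and Hoxa7, members of the cluster active in MLL-rearranged leukemia, were not measured for H3K27me3.

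Among developmental transcription factors, 25 of 92 measured genes were lower and 0 higher, with a median log2 ratio of -0.45 (interquartile range -0.60 to -0.33); 91 of the 92 lay below 0. Lhx2 had a ratio of 0.588 (0.536 to 0.645), Otx1 0.576 (0.502 to 0.660), Nkx6-2 0.513 (0.402 to 0.651) and Dlx1 0.453 (0.313 to 0.647). This list median lay at percentile 0.00 of random lists matched on level but at 20.9 of lists matched on read density. On the same match the medians of HoxA, HoxB, HoxC and HoxD lay at percentiles 0.49, 5.15, 1.96 and 6.05. Of the p53 targets 3 of 6 were lower with a median of -0.55, at percentile 0.19 of density-matched lists. These were Phlda3, Plk2 and Sesn1.

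Genes with dense H3K27me3 were lower in the deleted library as a class. The 10% of genes with the most H3K27me3 per kb held 14.2% (Wilson interval 14.1% to 14.2%) of floxed counts, 10.8% (10.8% to 10.9%) of deleted counts and 13.1% (13.1% to 13.1%) of rescue counts. In that class the median log2 ratio of deleted against floxed was -0.42, and 251 genes were lower against 3 higher. In class 4 of 10, at lower density, the median was 0.20, and 98 genes were higher against 22 lower.

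**Figure D2:**
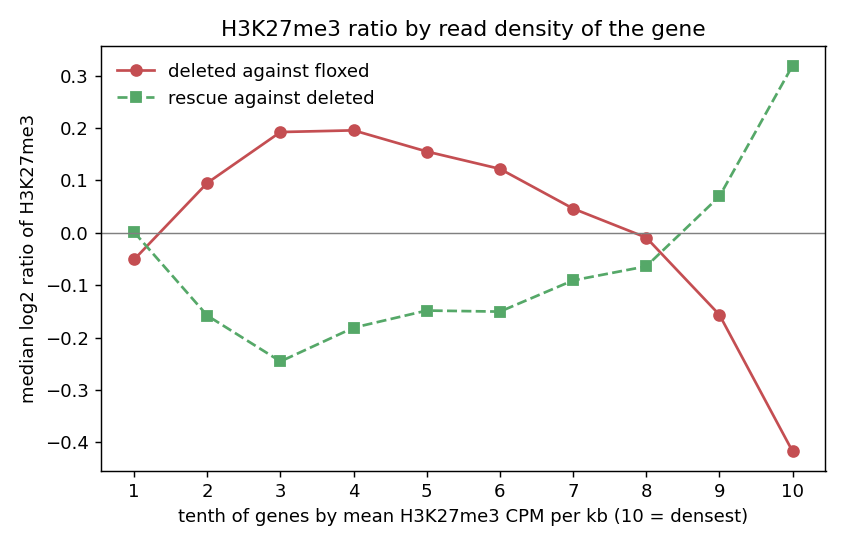
Median log2 ratio of H3K27me3 (vertical axis) for genes in 10 equal classes of mean H3K27me3 CPM per kb (horizontal axis, 10 the densest); the red solid line is deleted against floxed and the green dashed line rescue against deleted. In the densest class the medians were -0.42 and 0.32.

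Other lists showed smaller H3K27me3 differences between deleted and floxed. Median log2 ratios were -0.25 for granulocyte and monocyte maturation genes (1 of 8 lower, Mmp9), -0.11 for PRC1 genes (1 of 8 lower, Bmi1, with 87, 55 and 164 counts), -0.02 for stem and progenitor genes (2 of 18 lower, among them Mycn with a ratio of 0.547) and -0.01 for MLL fusion targets (2 of 12 lower, among them Cdk6, and 1 higher, Bcl2). Lists of other cell types lay near 0, at 0.06 for B-cell genes, 0.05 for T-cell and NK-cell genes, 0.17 for erythroid and megakaryocyte genes, 0.02 for mast cell, basophil and eosinophil genes, 0.01 for stromal and endothelial genes and -0.02 for neuronal genes. The medians were 0.12 for VEGF signalling genes, 0.10 for interferon-stimulated genes, 0.08 for germline genes, -0.36 for 2 PRC2 genes and 0.10 for olfactory receptor genes. For 5 proliferation genes the median was -0.00, at percentile 39.1, and 1 was lower, Ccnd2, with 83, 30 and 74 counts.

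Re-expression of Flag-tagged Hhex went with higher H3K27me3 at the named loci with the largest losses, and other loci went far past the floxed library. Chpf, Naaa, Sbf2 and Tmem198 did not differ from the floxed library by the size rule, and Airn was higher than floxed, with a ratio of 1.52 (1.4 to 1.66). Far above the floxed library, Jup, which encodes plakoglobin (chromosome 11, 100368856 to 100397839), had 47, 14 and 1022 counts and its neighbour Nt5c3b 7, 6 and 996, a ratio of 100 (45.8 to 274) against deleted. Slc28a2, a nucleoside transporter gene, had 35, 12 and 923 counts, and Limd1 52, 10 and 698. In the other direction, Hoxb4, a stem cell regulator, had 35, 24 and 1 counts, a ratio of 0.0251 (0.000611 to 0.154) against deleted, and the overlapping Hoxb3 229, 231 and 110. Ica1 had 203, 239 and 48 counts and Nrp2 225, 258 and 51. Prex1 had a ratio of 0.111 (0.0967 to 0.128) and ended below the floxed library as well.

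In all, 1196 genes were lower and 750 higher in H3K27me3 in rescue against deleted; edgeR TMM factors gave 991 and 935, and scaling to a background list 3522 and 286, which put the median of all genes at -0.44 in place of -0.06. The median log2 ratio was 1.41 for CDK inhibitors, 0.98 for HoxA, 0.32 for HoxB, 0.50 for HoxC, 0.52 for HoxD and 0.36 for developmental transcription factors (14 of 92 higher, 6 lower). By the size rule 3 CDK inhibitor genes were higher and 1 lower, Cdkn2c at -1.28, 3 HoxA genes were higher and 1 lower, 1 HoxB gene higher and 2 lower, and 2 HoxC and 3 HoxD genes higher. Among density-matched lists the medians of HoxB, HoxC, HoxD and developmental transcription factors lay at percentiles 42.7, 84.0, 92.1 and 78.3, and those of CDK inhibitors and HoxA at 99.99 and 99.95. Of the 572 genes lower in deleted against floxed, 280 (49.0%) had a rescue to deleted ratio of at least 1.5, and of the 500 higher genes 254 (50.8%) had a ratio of at most 1 divided by 1.5. With counting noise alone these shares were 38.6% and 20.5%, and with library labels shuffled within each gene 47.6% and 32.3%. Scaled to the background list they were 12.0% and 85.0%. By the size rule in both comparisons, 242 genes were lower and then higher, against 40.5 for independent lists and 294 with shuffled labels, and 234 were higher and then lower, against 56.4 and 214. The covariance of the log2 ratios of both comparisons was -0.144, against -0.0349 for counting noise and -0.142 with shuffled labels. Part of the excess over independent lists may come from the shared deleted library, which counting noise and shuffled labels share as well. For lower genes the number did not exceed that of shuffled labels (242 against 294), and the shares were close (49.0% against 47.6%). For higher genes both values lay above those of shuffled labels. Shuffled labels keep real differences, so they cannot decide whether the return was real. In rescue against floxed, 854 genes were lower and 607 higher; with a mean of at least 100 counts these were 268 and 276, and with a background list 5382 and 154. The rescue library lay below both others at 559 genes and above both at 347, the deleted library at 242 and 234, and the floxed library at fewer genes of each kind.

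H3K4me3 was higher in the deleted library at Adm, with 23, 84 and 6 counts and a ratio of 5.60 (3.50 to 9.31) for deleted against floxed, and at the anion exchanger gene Slc4a3, with 28, 51 and 6 counts and a ratio of 2.79 (1.73 to 4.60). Other genes picked by the ranking of higher values were the histone genes Hist1h1b, with 61, 104 and 42 counts, Hist1h2ai, with 23, 41 and 18, and Hist1h3c, with 38, 57 and 18; near-identical copies of these genes may share reads. H2-Q6, Cd80, Tcf15, Ccdc151 and Ighv8-12 had ratios of 2.04, 2.64, 2.24, 2.75 and 3.31. Lower in the deleted library were the window at the microRNA gene Mir210, with 137, 32 and 73 counts and a ratio of 0.358 (0.236 to 0.530), the histone variant gene H3f3b, with 55, 10 and 20, and the nuclear pore gene Ndc1, with 40, 7 and 16. Nlrp3 had 40, 8 and 20 H3K4me3 counts, a ratio of 0.307 (0.124 to 0.664). Ccdc12, Lmbrd1, Pnkd, Smpdl3a, Ube3a and Xcr1 had ratios between 0.288 and 0.426.

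By list, granulocyte and monocyte maturation genes had a median H3K4me3 log2 ratio of -0.24 over 15 genes in deleted against floxed, at percentile 3.52 of level-matched lists. Elane, which encodes neutrophil elastase, had 91, 28 and 58 counts, and Ly6c2 42, 14 and 18; these 2 of the 15 were lower by the size rule, and Ctsg had a log2 ratio of -0.54. In rescue against deleted the median was 0.38, at percentile 99.8, with Elane and Irf8 higher. For H3K27me3 in that comparison, 4 of 8 measured genes of this list were higher and 2 lower. Their median was 0.31, at percentile 98.2 of level-matched and 87.3 of density-matched lists. Developmental transcription factors lay the other way in deleted against floxed, with a median of 0.23 over 22 genes at percentile 99.9. Foxl2, Lhx2 and Six2 were higher by the size rule and Evx2 was lower. Housekeeping genes had a median of -0.19 over 16 genes, at percentile 11.9, and in rescue against deleted 0.21, at percentile 95.3, with 4 higher and 1 lower.

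Of 6681 genes measured for H3K4me3, 293 were lower and 202 higher in deleted against floxed. Counting error simulated with no difference gave 77.9 lower and 70.2 higher genes. With edgeR TMM factors the observed numbers were 403 and 139, and with a background list 398 and 140. In rescue against deleted 399 were lower and 300 higher; with a background list these were 133 and 1555, which put the median of all genes at 0.39 in place of 0.03. With predicted genes skipped, the 5 higher genes whose intervals lay farthest from 1 were Pgk1, a glycolytic enzyme gene with 39, 19 and 73 counts, Mgam, Fkbp2, the acetyltransferase gene Kat6a and the translation factor gene Eef1a1. The lower genes in this comparison were led by Slc28a2, with 37, 50 and 1 counts, Rad17, with 37, 25 and 0, Adm, Slc4a3 and the myelin gene Pmp22, with 125, 105 and 18. A return of at least 1.5 was seen in 54.9% of the 293 lower and 61.9% of the 202 higher genes, against 41.8% and 25.8% with counting noise and 46.2% and 25.9% with shuffled labels; with a background list the shares were 85.2% and 40%. The richest 10% of windows held 19.4%, 19.5% and 20% of counts in floxed, deleted and rescue.

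At single loci both marks moved in opposite directions. Adm was lower in H3K27me3 and higher in H3K4me3 in the deleted library, and the reverse in rescue against deleted; Nlrp3 showed the mirror image. Slc28a2 and Pmp22 gained H3K27me3 in the rescue library and had lower H3K4me3 there. Across the 2317 genes measured for both marks, the log2 ratios of deleted against floxed had a Pearson correlation of -0.06, and those of rescue against deleted -0.16; genes are not independent replicates. Of 227 such genes higher in H3K27me3 in rescue against deleted, 47 (20.7%) were lower in H3K4me3 and 10 (4.41%) higher, against 12.0% and 2.99% of genes without an H3K27me3 call. Of 186 genes lower in H3K27me3 in deleted against floxed, 12 (6.45%) were higher in H3K4me3 and 6 (3.23%) lower, against 5.61% and 2.54% of genes without an H3K27me3 call.

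Flag summits of the rescue library alone lay mostly away from gene ends, as random positions and the summits of the other libraries did. Of 429 rescue summits, 205 (47.8%) had no floxed or deleted summit within 250 bp; the floxed library, with no tagged Hhex per the labels, had 262 of 475 of its own and the deleted library 58 of 220. Among the rescue-alone summits with high scores were those in Snx6 (chromosome 12, 54774995, score 35.7), in 4930578N18Rik (chromosome 16, 76143297, score 33.8), 2100 bp from Gm52787 (chromosome 5, 122193669, score 27.2), and 17092 bp from F11r (chromosome 1, 171481685, score 21.9). A summit on chromosome 12 at 20699564, 28873 bp from LOC108167368, had a score of 17.2. Summits in Cntnap5b and Lrrc4c and 189211 bp from Olfm3 scored below 10.

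No Flag summit lay within 100 kb of Cdkn2a in any of the 3 libraries, and the nearest rescue summit was 497 kb away. With 429 rescue summits over the whole genome, most regions of this size hold none. The absence therefore cannot show whether tagged Hhex binds at Cdkn2a. Of the 205 rescue-alone summits, 9 (4.39%, exact interval 2.03% to 8.17%) lay within 1 kb of a gene end, against 5.03% of 10000 random positions, 2.53% of floxed and 5% (2.52% to 8.77%) of deleted summits. Gene spans held 30.7% (24.5% to 37.5%) of rescue-alone, 30.5% of floxed and 29.5% of deleted summits, against 46.3% of random positions. The 53 measured genes at the rescue-alone summits had a median H3K27me3 log2 ratio of 0.09 in deleted against floxed, at percentile 85.8 of level-matched lists, with 3 lower and 0 higher. For the 12 genes measured for H3K4me3 the median was -0.06, at percentile 29.2. Of the 50 rescue summits with the highest scores, 36 were in all 3 libraries and 7 in the rescue library alone.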

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

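The alternatives were planned before the data were examined, except thinning, removal of the density trend and leaving out overlapping genes, which were added afterwards. Background scaling was planned as a median ratio over list members. It was changed to pooled counts once nearly no member proved to be measured. No paired analysis was possible because each group held 1 library. The side with more genes changed under some alternatives, so no majority of lower over higher genes held under all of them. The cause was not tested for the values that moved, except that a filter or a 2-fold rule calls other numbers of genes by construction.

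For H3K27me3 in deleted against floxed (572 lower, 500 higher), background scaling gave 1239 and 226, a mean of at least 100 counts 324 and 107, a 2-fold rule 145 and 177, and no filter 774 and 840; 331 were higher with the density trend removed. In rescue against deleted (1196 lower, 750 higher), background scaling gave 3522 and 286, a mean of at least 100 counts 384 and 430, a 2-fold rule 484 and 323, and no filter 1149 higher. For H3K4me3 in deleted against floxed (293 and 202), a mean of at least 100 counts gave 5 and 2, a 2-fold rule 70 and 42, no filter 354 and 507, and DESeq2 size factors 248 and 253. In rescue against deleted (399 and 300), background scaling gave 133 and 1555, a mean of at least 100 counts 30 and 14, a 2-fold rule 194 and 80, and no filter 629 lower. Thinning all libraries of a mark to the smallest gave 527 lower and 457 higher H3K27me3 genes in deleted against floxed. Of these, 503 and 428 were among the genes called without thinning. For H3K4me3 it gave 246 lower and 169 higher genes. Of these, 164 and 112 were called without thinning, 56.0% and 55.4% of the genes called then.

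The share of lower H3K27me3 genes that came back (49.0%) was 56.3% with edgeR TMM factors, 54.9% with DESeq2 size factors, 12.0% with background scaling, 57.1% with no filter and 54.1% with the density trend removed. For higher genes (50.8%) it was 85.0% with background scaling, 59.5% with no filter and 32.2% with the 2-fold rule. For H3K4me3 the share for lower genes (54.9%) was 85.2% with background scaling, 48.6% with the 2-fold rule and 48.4% after thinning. For higher genes (61.9%) it was 40% with background scaling, 73.8% with no filter, 50% (of 2 genes) with a mean of at least 100 counts and 53.3% after thinning.

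Cdkn2a kept its direction in H3K27me3 under every alternative run. Its log2 ratio in deleted against floxed was -1.54 with the density trend removed, and in rescue against deleted 1.58 with background scaling. The correlation between marks in deleted against floxed was -0.0219 with a mean of at least 100 counts and -0.0193 in the 10% of genes richest in H3K27me3. The richest 5% of genes held 6.42%, 4.55% and 5.99% of H3K27me3 counts and 11%, 11.1% and 11.5% of H3K4me3 counts in floxed, deleted and rescue. Summits above the median score of their list left 85 in the rescue library alone, and a median H3K4me3 log2 ratio of 0.13 at their genes, in place of -0.06. Of 182 ratios of other named genes that met the size rule, 181 met it with TMM factors, 181 with size factors, 182 with a prior count of 5 and 156 with background scaling. H3K4me3 has the lower depth, which limits ratios of genes near 20 counts.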

Other observations

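The rescue library held H3K27me3 at genes where both other libraries had far less; these genes were chosen after their values were seen. Mpo, which encodes the myeloperoxidase of neutrophil granules (chromosome 11, 87793784 to 87804412), had 5, 6 and 483 H3K27me3 counts in floxed, deleted and rescue and 89, 49 and 32 H3K4me3 counts. The nearby Rnf43, a regulator of Wnt receptors, had 21, 12 and 323 H3K27me3 counts and 175, 114 and 59 H3K4me3 counts. Samd4 (chromosome 14, 46882965 to 47105817) had 943, 340 and 8334 H3K27me3 counts and 153, 127 and 32 H3K4me3 counts. Other genes of this kind were Ctdspl, with 43, 53 and 2049 H3K27me3 counts, Tnk2, with 16, 16 and 543, and Vamp4, with 3, 10 and 493. In rescue against floxed, H3K4me3 did not meet the size rule at Ctdspl (231, 159 and 111 counts) or Tnk2 (193, 116 and 84). Vamp4 differed in that its H3K4me3 was higher in rescue against floxed, with 114, 74 and 137 counts.

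Differences in H3K27me3 ran over neighbouring genes. Among 6460 pairs of adjacent measured genes that do not overlap and lie within 100 kb, 62 pairs had both members lower in deleted against floxed, where shuffled calls gave a mean of 18.5 and a maximum of 33 in 1000 shuffles. The shuffles ignored read density. As 251 of these lower genes were in the densest class of 10, neighbouring dense genes could give part of this excess. For genes higher in rescue against deleted 104 pairs were seen, against a mean of 31.2. For genes lower in rescue against deleted there were 133 pairs, against a mean of 83.0 and a maximum of 114. For genes higher in deleted against floxed the number was 24, above the mean of 14.2 but within the maximum of 27 that shuffles gave.

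All tests below were chosen after the result was seen.

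Lower H3K27me3 in the deleted library could come from weaker enrichment of that immunoprecipitation, from lost DNA or from a change at these genes. With the median of genes of like read density removed, Cdkn2a kept a log2 ratio of -1.54 (-1.81 to -1.30), which argues against weaker enrichment as its whole cause. For the developmental transcription factors the list median lay at percentile 20.9 of density-matched lists, as weaker enrichment predicts and as a graded loss of the mark would also give. Over all lower genes 51.7% stayed lower, between the bounds of 25% and 75% set before this test was run, so these cannot be told apart for the rest. Lost DNA would lower both marks, and the 186 lower genes with H3K4me3 values had a median H3K4me3 log2 ratio of 0.0871. That median describes these genes as a set and cannot settle single loci. Cdkn2a had an H3K4me3 log2 ratio of -0.56, not called by the size rule. Chpf, Adam28 and Cdkn2b were not measured for H3K4me3. Variation between single libraries stays open with 1 library per group. Shuffled labels (702 lower genes on average) cannot decide it because they keep real differences.

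In H3K27me3 the rescue library lay above both others at 347 genes and below both at 559; a change specific to the rescue cells is a candidate for the 347. After thinning, 79.5% of the 347 stayed higher than both, so most of these calls did not need the greater depth. The thinned counts were drawn from the same reads, so this is no separate check of the calls. Error in the H3K27me3 library alone would leave H3K4me3 as at other genes, yet 19.4% (12.1% to 28.6%) of 98 such genes were lower in H3K4me3 in rescue against floxed, against 6.04% of other genes. This interval takes genes as independent draws, while H3K27me3 calls ran over neighbouring genes, so it may be too narrow. The other genes were also not matched on H3K4me3 level, so the excess cannot exclude such error. Bound tagged Hhex was looked for near these genes: 0.296% (0.00749% to 1.64%) had a rescue-alone summit within 10 kb, where gene length predicts 0.590%, and 1 gene is too few to tell. A difference between cell lines that arose during culture may remain, and was not tested.

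The Flag summits at Hhex were in every library. All 3 Hhex summits of the rescue library had a partner in the floxed and in the deleted library, so tagged Hhex cannot be their whole source. At Pgk1 (chromosome X, position 106187015) the rescue summit had the score of rank 2 in its list, with a partner in the floxed list and none in the deleted list. A candidate explanation is vector sequence with a Pgk1 promoter in the rescue cells; the H3K4me3 ratio at Pgk1 of 3.06 (2.04 to 4.63) in rescue against floxed goes with it, and a higher mark at the gene itself would look the same.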
